A study of Mus musculus with 39 samples.

How the data were processed

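Polyadenylated RNA from mouse brain was measured in 39 libraries made, per the labels, with a TruSeq Stranded mRNA kit. The labels give the tissue as brain, but the extraction text speaks of a cell pellet, and the dissected region is not given in the sources used here. Per the submitters' processing notes, reads were aligned with GSNAP to GRCm38; their versions, the counting tool, the annotation release, the strand setting and any read filter are not given in the sources used here. Each deposited file gives, for 52636 Ensembl genes listed alike in all libraries, whole-number read counts, the width of the gene in bases, and RPKM (reads scaled to gene width and library total). The deposited RPKM implied a denominator larger than the sum of the deposited counts, which made up 86.1 to 88.2% of it. The counts were analysed, and RPKM was used only for that check. Since the strand setting is not given, reads from overlapping genes on opposite strands cannot be assigned with certainty. Near-identical genes, such as Hba-a1 and Hba-a2 or the class I H2 genes, can exchange reads.

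The labels defined 9 groups. Each of 8 treatments was compared with saline, and ASO 1 to ASO 4 were compared with each other in pairs, which made 14 comparisons. Symbols were given for 52403 of the genes; positions came from GENCODE M21 on GRCm38 and were found for 19211 of the 19246 genes tested. Genes were kept by filterByExpr of edgeR 4.0.16 under R 4.3.3 and scaled by TMM. Group differences were tested with edgeR's quasi-likelihood test in a single design of 9 groups, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. All adjusted p-values without another name come from that test, which is two-sided. Log2 fold changes carry a standard error (SE), derived as the size of the change divided by the square root of the test's F statistic. Confidence intervals rest on that value. Levels are CPM, counts scaled to a common library total, with the standard deviation (SD) between libraries. Means of gene lists are on the log2 CPM scale with a prior count of 2.

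Before the data were examined, 38 lists holding 559 genes were fixed for cell types, brain regions, glial states and pathways; all 559 genes were found. The 29 lists with at least 10 tested genes were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. The genes named were also fixed by rule at that stage. Tmem106b, Grn, Tmem106a and Tmem106c were always given. For ASO 1 to ASO 4 against saline, up to 8 rises and 8 falls with the largest changes past the threshold were named, each with a mean of at least 1 CPM in the higher group and no overlap between the groups. Up to 4 members per list with the smallest adjusted p were added. The limits were 4 rises, 4 falls and 2 list members for coded treatments and 3 genes each way between ASOs; predicted genes and pseudogenes were passed over, and a few genes that the rule names are not reported here. Genes outside the rule are said to be chosen after their values were seen.

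Counts summed to 34.0 ± 3.90 M (mega) per library (SD, n = 39). The test was checked on simulated counts with 200 changed genes among 19246. It recovered 97 to 100% of changes of 2-fold and 78 to 90% of changes by the square root of 2 across the comparisons with saline. There were 4 to 13 false calls among 183 to 197. Simulated genes varied independently, and only genes of at least 1 CPM were changed. Differences between libraries shared by many genes were thus left out, and false calls in the real data may be more frequent. Alternatives fixed in advance were DESeq2 1.42.0, limma voom with sample quality weights, median-of-ratios scaling, no expression filter, fits of 2 groups only or of saline and ASO 1 to ASO 4 only, and leaving out each library. A sex term was planned and not run, since all 39 libraries had Y-linked transcripts and almost no Xist. Covariates for the striatum and hypothalamus list means, a fit without the 11 libraries with Pmch above 5 CPM, and an offset for GC content were added after the data were seen. The labels give no sex, age, genotype, dose, time or batch, and do not say whether libraries came from separate animals, so p-values measure the spread between samples.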

Results

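The series sequenced polyadenylated RNA of mouse brain after saline or antisense oligonucleotides (ASOs), short synthetic nucleic acids that pair with a transcript and can direct its cleavage. Its design text names Tmem106b, which encodes a lysosomal membrane protein, as the target. The 39 libraries comprised 5 given saline, 3 given ASO 1, 5 given ASO 2, 4 given ASO 3 and 5 given ASO 4. A further 17 libraries carried only a treatment code, with no ASO number and no stated target: RTR113609 (4 libraries), RTR113643 (5), RTR113841 (3) and RTR59155 (5). Summed counts per library ranged from 19.7 M (M, mega) in ASO 4 replicate 4 to 44.2 M in ASO 3 replicate 4. Group means ranged from 32.1 ± 7.51 M (SD, n = 5) in ASO 4 to 37.0 ± 4.84 M (SD, n = 4) in ASO 3, with 32.8 ± 1.79 M (SD, n = 5) in saline.

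The question put to each treatment against saline was how far Tmem106b fell and which other genes changed with it. Tmem106b (ENSMUSG00000029571, chromosome 6, 13069759 to 13089269 on the plus strand of GRCm38, a gene span of 19.5 kb) stood at 191.9 ± 15.6 CPM (SD, n = 5) in saline, and every treated library lay below every saline library. The lowest saline library had 171.2 CPM and the highest in ASO 4, RTR113643 and ASO 2 had 120, 116.5 and 104.9 CPM, with 1531 to 7624 counts behind the value of each library. ASO 1 left 53.3 ± 9.14 CPM (SD, n = 3), 72.2% below saline with a 95% confidence interval of 65.1 to 77.9% (log2 fold change -1.85, SE 0.16, adjusted p = 4.78e-10). ASO 3 left 76.2 ± 9.54 CPM (SD, n = 4), 60.3% lower (adjusted p = 3.14e-08), and ASO 2 left 89.8 ± 16.8 CPM (SD, n = 5), 53.2% lower (adjusted p = 4.01e-06). ASO 4 left 112.9 ± 6.38 CPM (SD, n = 5), 41.2% lower (log2 fold change -0.77, SE 0.13, adjusted p = 0.00543). Among the coded treatments Tmem106b was 69.8% lower in RTR59155 (57.9 ± 11.9 CPM, SD, n = 5) and 64.4% lower in RTR113609 (68.2 ± 15.7 CPM, SD, n = 4). It was 61.6% lower in RTR113841 (73.8 ± 9.65 CPM, SD, n = 3) and 49.4% lower in RTR113643 (97.1 ± 17.1 CPM, SD, n = 5). The largest adjusted p of these was 1.28e-05. Without the 11 libraries that had Pmch above 5 CPM, the ASO 4 fall no longer passed (log2 fold change -0.82, adjusted p = 0.0514).

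**Figure D1:**
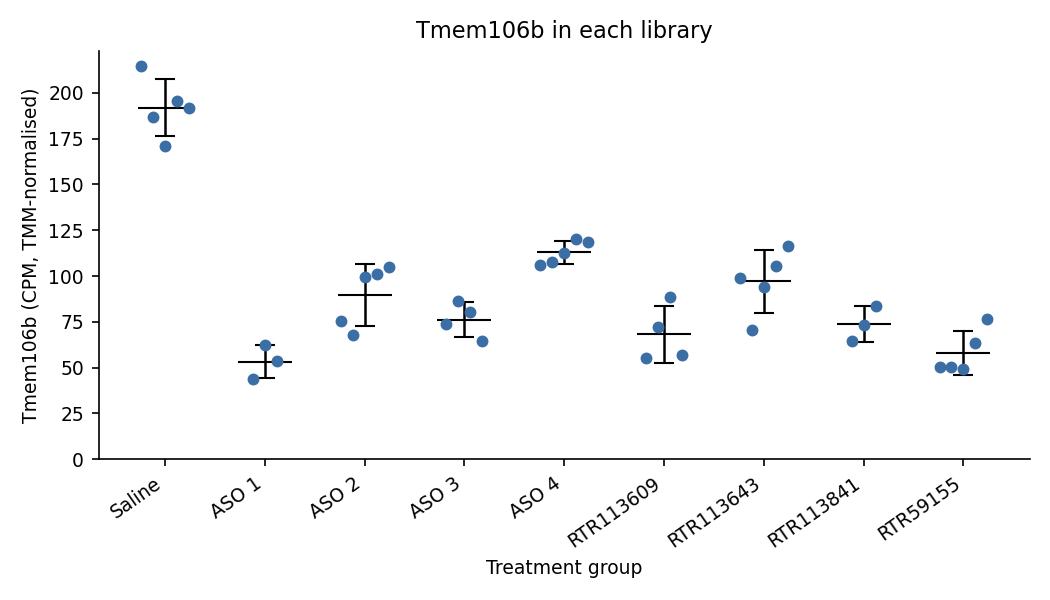
Tmem106b in CPM (vertical axis) for each of the 39 libraries by group, with the mean and SD of each group. All treated libraries lie below the lowest saline library at 171.2 CPM.

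Grn, the gene of progranulin, a secreted glycoprotein that reaches lysosomes, was examined because the series title sets TMEM106B beside GRN haploinsufficiency. The labels do not give the Grn genotype of the mice. Grn (ENSMUSG00000034708, chromosome 11, 102430315 to 102437048) stood at 89.1 ± 8.84 CPM (SD, n = 5) in saline. Among the 8 comparisons with saline it passed the threshold in ASO 3, where it rose to 118.5 ± 4.37 CPM (SD, n = 4; log2 fold change 0.41, SE 0.11, adjusted p = 0.0333). The ASO 3 call was lost in 7 of the fits that left out 1 library and with covariates for regional marker genes (log2 fold change 0.37, adjusted p = 0.0967). Grn had 120.5 ± 22.5 CPM in ASO 1 (log2 fold change 0.44, adjusted p = 0.0996), 110.6 ± 15.2 CPM in ASO 4 (0.31, adjusted p = 0.353) and 90.8 ± 13.3 CPM in ASO 2 (0.03, SE 0.10, adjusted p = 0.949). Its log2 fold changes in the coded treatments were 0.33 for RTR113609, 0.31 for RTR113643, 0.30 for RTR113841 and 0.39 for RTR59155, with adjusted p from 0.0547 to 0.556. Between ASOs, Grn was higher in ASO 1 than in ASO 2 (0.41, SE 0.12, adjusted p = 0.0193) and lower in ASO 2 than in ASO 3 (-0.39, SE 0.11, adjusted p = 0.0259). The paralogs Tmem106a (2.31 ± 0.607 CPM in saline) and Tmem106c (36.4 ± 1.16 CPM in saline) passed in none of the 8 comparisons with saline. The median over the 3 family members was 0.12 in ASO 1, opposite in sign to the fall of Tmem106b. In ASO 2, alone among the treatments, the means of both paralogs lay below saline (1.82 ± 0.38 and 34.15 ± 1.22 CPM, SD, n = 5). Tmem106c was higher in ASO 1 than in ASO 2 (0.21, adjusted p = 0.0128) and lower in ASO 2 than in ASO 3 and ASO 4 (-0.19 and -0.20, adjusted p = 0.0211 and 0.0303). Tmem106a was lower in ASO 2 than in ASO 3 (-0.67, adjusted p = 0.0215). All of these Grn, Tmem106c and Tmem106a calls between ASOs ended with those covariates (adjusted p from 0.373 to 0.933) and without the 11 libraries that had Pmch above 5 CPM (adjusted p from 0.269 to 0.964).

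Transcripts of hypothalamic neurons differed widely between libraries of the same group. Pmch, the precursor of melanin-concentrating hormone, exceeded 5 CPM in 11 libraries, where it ranged upward from 8.54 CPM, and was at most 1.64 CPM in the other 28. These 11, the high-Pmch libraries, were none of 5 saline libraries, 2 of 3 in ASO 1, 1 of 5 in ASO 2, 3 of 4 in ASO 3, 2 of 5 in ASO 4, none in RTR113609 and RTR113841, 1 of 5 in RTR113643 and 2 of 5 in RTR59155. The hypothalamus list mean was 1.14 ± 0.37 log2 CPM (SD, n = 5) in saline, 2.04 ± 1.15 (n = 3) in ASO 1 and 2.94 ± 1.01 (n = 4) in ASO 3. The striatum list mean was 7.62 ± 0.18 in saline, 7.20 ± 0.25 in ASO 1 and 7.18 ± 0.30 in ASO 3. Both list means served as regional covariates in an added fit.

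**Figure D2:**
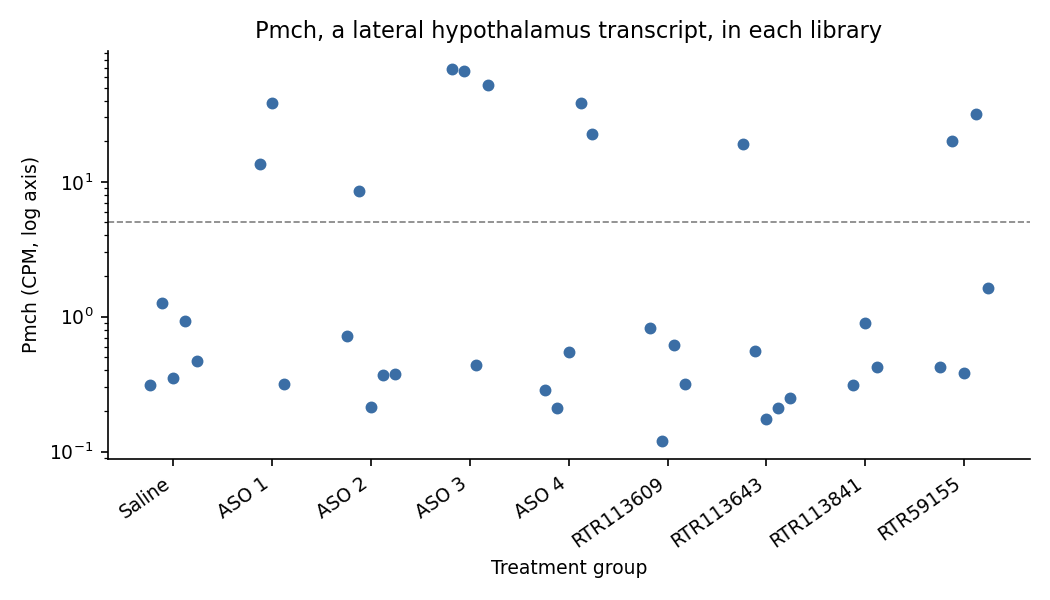
Pmch in CPM on a log axis for each library by group, with a dashed line at 5 CPM. The 11 libraries above the line include 3 of 4 in ASO 3 and 2 of 3 in ASO 1 and no saline library.

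In ASO 1 against saline, Nrxn3, Pcdh9 and Itsn1 were among the genes that fell beside the target. Nrxn3, which encodes a presynaptic adhesion molecule, fell by 59.2% to 85.5 ± 3.43 CPM (SD, n = 3) from 209.5 ± 10.3 CPM (SD, n = 5; log2 fold change -1.29, SE 0.077, adjusted p = 1.03e-14). The protocadherin Pcdh9 fell to 62.0 ± 6.76 from 138.6 ± 12.2 CPM (-1.16, adjusted p = 1.08e-10), and Itsn1, an endocytic scaffold, fell to 109.9 ± 10.5 from 170.2 ± 4.11 CPM (-0.63, adjusted p = 2.13e-08). Fhit (-0.76), Pibf1 (-0.76), Cntln (-0.73) and Nudcd1 (-0.62) also fell, with the largest adjusted p at 0.00146. Among the rises, Gch1, the first enzyme of tetrahydrobiopterin synthesis, had a log2 fold change of 0.80 (SE 0.16, adjusted p = 0.0142), followed by Tmprss5 (0.71), the transcription factor Klf4 (0.71), Arid5a (0.48), Thsd1 (0.42) and Nfil3 (0.36). Trf (0.38, SE 0.081, adjusted p = 0.0188) and Mag (0.32, SE 0.066, adjusted p = 0.0146, 403 ± 25.3 against 323.2 ± 18.2 CPM) rose. Both belong to the list for oligodendrocytes and myelin, whose members are called myelin genes here for short. The other 18 of the 20 myelin genes did not pass. Adjusted over the list alone 2 were higher and 1 lower (camera adjusted p = 0.0311; adjusted p = 0.667 with an estimated correlation). None of 24 disease-associated microglia genes and none of 44 lysosomal genes passed over all genes. Adjusted over the list alone, 16 and 19 of them passed, all higher, with list medians of 0.51 and 0.13 (camera adjusted p = 9.2e-14 and 1.47e-14; adjusted p = 0.3 for both with an estimated correlation). All 10 striatum markers passed adjusted over the list alone and were lower, with a median of -0.43 (camera adjusted p = 1.15e-07; adjusted p = 0.3 with an estimated correlation), and none passed over all genes. Of 18 cholesterol synthesis genes none passed over all genes and 9 passed adjusted over the list alone, all higher (median 0.13, camera adjusted p = 2.05e-07; adjusted p = 0.3 with an estimated correlation).

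In all, 44 genes passed in ASO 1, 10 higher and 34 lower, and 3 of the falls were at least 2-fold. Camera called 15 of 29 lists (9 without ASO 1 replicate 1), none of which was called with an estimated correlation. The number of genes was 19, 27 and 118 without ASO 1 replicates 1, 2 and 3, 24 without saline replicate 1, 132 with DESeq2, 73 without the filter, 27 with 2 groups only, 26 with regional covariates and 10 without the high-Pmch libraries. Of 16 named calls, 8 ended without ASO 1 replicate 1, Nudcd1 among them (-0.54, adjusted p = 0.0673), 5 without replicate 2, 7, 2, 7, 1 and 1 without saline replicates 1 to 5, 7 with 2 groups only and 11 without the high-Pmch libraries. The 8 named rises were lost with the regional covariates, whereas Tmem106b, Nrxn3, Pcdh9 and Itsn1 passed under every alternative run. DESeq2 gave an adjusted p for 8 of the 16 named calls, all past the threshold, and called 35 of the 44 genes.

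ASO 2 against saline gave 14 genes in the edgeR fit of all groups, but 219 with DESeq2, 269 with limma voom and 221 with 2 groups only. Nrxn3 fell to 103.2 ± 8.61 CPM (SD, n = 5; log2 fold change -1.02, SE 0.064, adjusted p = 5.66e-14). Rbm5, a splicing regulator, fell by 0.40 on the log2 scale (SE 0.056, adjusted p = 5.27e-05), Abl1, a tyrosine kinase, by 0.38 (SE 0.047, adjusted p = 5.37e-06), and Mvb12b, an endosomal sorting subunit, by 0.30 (SE 0.042, adjusted p = 5.27e-05). Itsn1 (-0.29), Cntln (-0.37) and the Golgi protein gene Golgb1 (-0.20) fell with adjusted p from 0.0171 to 0.0305. The transcription factor gene Etv1 (0.39, adjusted p = 0.0385), Cmpk1 (0.30, adjusted p = 0.0484) and Nfyb (0.21, adjusted p = 0.0499) rose. No list member except Tmem106b passed over all genes. Adjusted over the list alone, 6 of 28 interferon response genes passed, all lower (median -0.21, camera adjusted p = 5.74e-06), and ASO 2 replicate 3 stood apart with a list mean of 1.55 log2 CPM against 1.74 to 1.80 in the other ASO 2 libraries. Of 14 immediate early genes 1 was higher and 6 lower adjusted over the list alone (median -0.40, camera adjusted p = 5.27e-05). So were 3 of 13 mitochondrially encoded genes, all higher (median 0.26, camera adjusted p = 2.8e-06). With an estimated correlation the adjusted p was 0.631 for each of these lists. Camera called 5 of 29 lists (8 without ASO 2 replicate 2), and none was called with an estimated correlation or by fry.

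Of the 14 genes past the threshold in ASO 2, 5 were higher and 9 lower; with median-of-ratios scaling 2 of 10 were higher, or 20% against 35.7%. DESeq2 called 219, limma voom 269, the fit of 2 groups 221, the fit of saline and ASO 1 to ASO 4 78, the fit without a filter 59, the GC offset 29, the regional covariates 22 and the fit without high-Pmch libraries 8. Without ASO 2 replicates 1, 2, 3 and 4 the number was 6, 5, 5 and 25, and without saline replicates 1 to 5 it was 24, 8, 8, 5 and 6. Cmpk1 and Nfyb no longer passed with median-of-ratios scaling (adjusted p = 0.0507 and 0.0537), and the rises, Cntln and Golgb1 were lost without the high-Pmch libraries and in at least 7 fits that left out 1 library, while Tmem106b, Nrxn3, Rbm5, Abl1 and Mvb12b passed under every alternative run.

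ASO 3 against saline had the most changes of the numbered ASOs, with 367 genes, 136 higher and 231 lower. Ctnna2, which encodes a neuronal catenin linking cadherins to actin, fell by 70.9% to 50.8 ± 5.12 CPM (SD, n = 4) from 174.1 ± 6.80 CPM (SD, n = 5; log2 fold change -1.78, SE 0.06, adjusted p = 2.7e-23). Kcnq5, a potassium channel gene, fell to 44.7 ± 7.24 from 100.5 ± 2.09 CPM (-1.17, SE 0.082, adjusted p = 4.13e-13). Immediate early genes, which neurons transcribe within minutes of activity, were lower: 8 of 14 fell over all genes and 12 were lower and 1 higher adjusted over the list alone. Among them were Egr2 (-1.73, SE 0.34, adjusted p = 0.00264), Npas4 (-1.51), Arc (-1.39), Fos (-1.26) and Egr1 (-0.87), and the list median was -0.86 (camera adjusted p = 3.42e-10; adjusted p = 0.235 with an estimated correlation). Hemoglobin transcripts of red blood cells rose, with Hbb-bs at 29.5 ± 18.4 CPM (SD, n = 4) against 3.00 ± 1.45 CPM (SD, n = 5; log2 fold change 3.28, SE 0.72, adjusted p = 0.0094). Hba-a1, Hba-a2, Hbb-bt and Alas2 rose by 3.00 to 3.33, and 5 of the 6 erythrocyte genes rose in all, over all genes and adjusted over the list alone (median 3.18). Hypothalamic peptide genes rose as well: Pmch had 46.7 ± 31.7 against 0.666 ± 0.418 CPM (adjusted p = 0.0141), and Hcrt, the orexin gene, had 11.7 ± 8.39 against 0.0784 ± 0.0918 CPM (adjusted p = 0.00747). Pomc and Ghrh had log2 fold changes of 2.18 and 1.94. In all, 4 of 10 hypothalamus markers rose over all genes and 5 were higher adjusted over the list alone (median 1.19, camera adjusted p = 2.04e-05; adjusted p = 0.235 with an estimated correlation). Ppp1r1b (-0.45, SE 0.13) was the striatum marker that fell, and all 10 were lower adjusted over the list alone (median -0.44, camera adjusted p = 2.19e-08; adjusted p = 0.255 with an estimated correlation).

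Glial and stress genes also changed in ASO 3. Of 24 disease-associated microglia genes 6 rose, among them Itgax (1.40, SE 0.32, adjusted p = 0.0129), Ccl6 (1.11), Tyrobp (0.67) and Ctsd, a lysosomal protease gene at 632 ± 59.4 against 435.8 ± 55.5 CPM (0.54, adjusted p = 0.0167). In all 18 were higher adjusted over the list alone (median 0.51, camera adjusted p = 3.22e-15; adjusted p = 0.235 with an estimated correlation). Of 44 lysosomal genes 6 rose, including Ctsl (0.25) and Npc2 (0.23), and 16 were higher adjusted over the list alone (median 0.11, camera adjusted p = 6.19e-10; adjusted p = 0.235 with an estimated correlation). The p53 target list had 3 rises among 16 genes, in Cdkn1a, an inhibitor of cell cycle kinases (31.4 ± 8.45 against 19.1 ± 2.05 CPM; 0.72, SE 0.11, adjusted p = 0.000107), Gtse1 (0.91) and Phlda3 (0.27). Adjusted over the list alone 6 were higher, and this list also passed with an estimated correlation (median 0.18, camera adjusted p = 1.62e-06; adjusted p = 0.00633 with an estimated correlation). ASO 3 replicate 4 stood apart in this list's mean, at 3.86 log2 CPM against 3.72 to 3.73 in the other ASO 3 libraries. Myelin genes moved both ways, with 4 rises, such as Trf (0.54) and Gjb1 (0.36), and 3 falls, such as Mal (-0.59, SE 0.076, adjusted p = 2.48e-06) and Cldn11 (-0.49), among 20. The counts were 5 higher and 6 lower adjusted over the list alone; the list median was 0.019 and its mean -0.019 (camera adjusted p = 0.994, fry mixed adjusted p = 9.46e-05). Of 22 reactive astrocyte genes Cd44 (0.82) and Gfap (0.61, SE 0.16, adjusted p = 0.0358) rose and 3 were higher adjusted over the list alone (camera adjusted p = 0.00181; adjusted p = 0.561 with an estimated correlation). Of 20 endoplasmic reticulum stress genes Ddit3 (0.27) and Sdf2l1 (0.43) rose and 4 were higher adjusted over the list alone (camera adjusted p = 0.00263; adjusted p = 0.419 with an estimated correlation). Cd163 (-0.95) and Mrc1 (-0.62) fell among 9 border macrophage genes, and 3 were lower adjusted over the list alone. Lhx6 (-0.38) and Gad1 (-0.20) fell among 12 inhibitory neuron genes, and 4 were lower adjusted over the list alone (camera adjusted p = 0.0508).

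Camera called 14 of 29 lists in ASO 3, 1 of them also with an estimated correlation. The number of genes was 117, 176, 651 and 160 without ASO 3 replicates 1 to 4, 204 and 217 without saline replicates 1 and 3, 557 with DESeq2, 934 with limma voom, 596 with 2 groups only, 121 with regional covariates and 27 without the high-Pmch libraries. Of 44 named calls, 31 ended without ASO 3 replicate 1, 18 without replicate 2, 10 without replicate 4, 14, 10, 11 and 7 without saline replicates 1, 3, 4 and 5, and 37 without the high-Pmch libraries. The fit of saline and ASO 1 to ASO 4 only ended 9 of these calls. The covariates ended 33, of which Pmch, Hcrt, Pomc and Ghrh belong to the hypothalamus list behind the covariate, so their loss carries no information. Ppp1r1b belongs to the striatum list behind the other covariate, so its call in that fit carries none either. Pmch had a log2 fold change of -0.23 there (adjusted p = 0.976) and of -0.60 without the high-Pmch libraries, which were chosen by Pmch itself. The hemoglobin genes no longer passed with the covariates or without ASO 3 replicate 1 (Hbb-bs 2.87, adjusted p = 0.0602), and Tmem106b, Ctnna2, Kcnq5, Mal, Cldn11 and Cdkn1a passed in all of these fits.

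In ASO 4 against saline 3 genes passed with edgeR, all lower. Beside Tmem106b, Nudcd1 fell to 9.941 ± 1.2 from 16.4 ± 1.17 CPM (SD, n = 5 each; log2 fold change -0.72, SE 0.093, adjusted p = 2.35e-05). Tmeff2, which encodes a transmembrane protein with follistatin-like domains, fell to 57.7 ± 2.47 from 74.6 ± 2.80 CPM (-0.37, SE 0.042, adjusted p = 1.81e-06). No gene of a list except Tmem106b passed over all genes. Adjusted over the list alone, 16 of 24 disease-associated microglia genes were higher (median 0.42, camera adjusted p = 8.05e-14; adjusted p = 0.175 with an estimated correlation). So were 8 of 16 homeostatic microglia genes (median 0.19, camera adjusted p = 5.01e-09; adjusted p = 0.17 with an estimated correlation). The same correction passed 5 of 28 interferon response genes, all higher (median 0.22, camera adjusted p = 1.31e-10; adjusted p = 0.17 with an estimated correlation). It also passed 7 of 12 choroid plexus genes, all higher (median 0.36, camera adjusted p = 5.28e-08; adjusted p = 0.2 with an estimated correlation). The 10 striatum markers, of which none passed over all genes or adjusted over the list alone, had a median of -0.22 (camera adjusted p = 2.87e-05; adjusted p = 0.32 with an estimated correlation). The hypothalamus markers had a median of -0.018 and a mean of 0.88 (camera adjusted p = 0.958). Camera called 15 of 29 lists, none with an estimated correlation and 2 by fry. The number of genes was 13 with DESeq2, 6 without the filter and 5 without saline replicate 2; Nudcd1 and Tmeff2 passed without each single library.

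RTR113609 against saline asked what this coded treatment changed, and gave 1294 genes, 454 higher and 840 lower. All 28 interferon response genes rose, with a median log2 fold change of 1.94 (camera adjusted p = 9.59e-92; adjusted p = 5.68e-06 with an estimated correlation), and all 28 passed adjusted over the list alone. Isg15, a ubiquitin-like modifier, had 14.5 ± 2.38 CPM (SD, n = 4) against 2.13 ± 0.468 CPM (SD, n = 5; 2.76, SE 0.16, adjusted p = 4.22e-16). Oas3 (2.68), Usp18 (2.61) and Zbp1 (2.55) were also among the largest rises. Of 16 MHC class I genes 12 rose over all genes and 15 were higher adjusted over the list alone (median 0.75, camera adjusted p = 1.15e-20; adjusted p = 0.0204 with an estimated correlation), with B2m at 243.3 ± 8.69 against 131.3 ± 15.9 CPM. Of 14 chemokine and cytokine genes 4 rose, among them Cxcl10 (2.28) and Ccl12 (2.02), and 5 were higher adjusted over the list alone (camera adjusted p = 4.85e-06; adjusted p = 0.154 with an estimated correlation). Of 13 complement genes 4 rose, such as C4b (0.82) and C1qa (0.71), and 1 fell; adjusted over the list alone 8 were higher and 1 lower (camera adjusted p = 0.00054; adjusted p = 0.406 with an estimated correlation). Of 16 homeostatic microglia genes 5 rose, such as Ltc4s (0.69) and Siglech (0.39), and 5 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000525; adjusted p = 0.41 with an estimated correlation).

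Other cell types had falls in RTR113609. Gpc5, which encodes an astrocyte-enriched glypican, fell to 8.04 ± 4.77 from 52.0 ± 6.81 CPM (log2 fold change -2.68, SE 0.18, adjusted p = 6.26e-14), and F13a1 (-1.52) and Egr2 (-1.51) fell too. Of 14 astrocyte markers 7 fell, such as Slc7a10 (-0.41) and Slc4a4 (-0.40), and 1 rose; adjusted over the list alone 9 were lower and 1 higher (median -0.23, camera adjusted p = 4.85e-06; adjusted p = 0.24 with an estimated correlation). Of 20 myelin genes 6 fell, including Mbp (-0.35), and Trf rose (0.37); adjusted over the list alone 10 were lower and 2 higher (camera adjusted p = 0.0172; adjusted p = 0.597 with an estimated correlation). Oligodendrocyte precursor genes had 5 falls among 13, with Lhfpl3 (-0.86) and Vcan (-0.35), and the same number adjusted over the list alone (camera adjusted p = 0.000525; adjusted p = 0.24 with an estimated correlation). Of 18 cholesterol synthesis genes 7 fell and 11 were lower adjusted over the list alone (median -0.20, camera adjusted p = 7.22e-07; adjusted p = 0.24 with an estimated correlation). Immediate early genes had 5 falls among 14, with Nr4a1 (-1.09) lost without saline replicate 4 (-0.86, adjusted p = 0.0566), and 8 were lower adjusted over the list alone (camera adjusted p = 0.000107; adjusted p = 0.406 with an estimated correlation). Camera called 18 of 29 lists, 2 of them also with an estimated correlation, and no alternative moved the number of genes by over 1.5 times. Of 47 named calls, 7, 8, 3 and 7 ended without RTR113609 replicates 1 to 4, and 2, 2, 5, 7 and 5 without saline replicates 1 to 5.

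**Figure D3:**
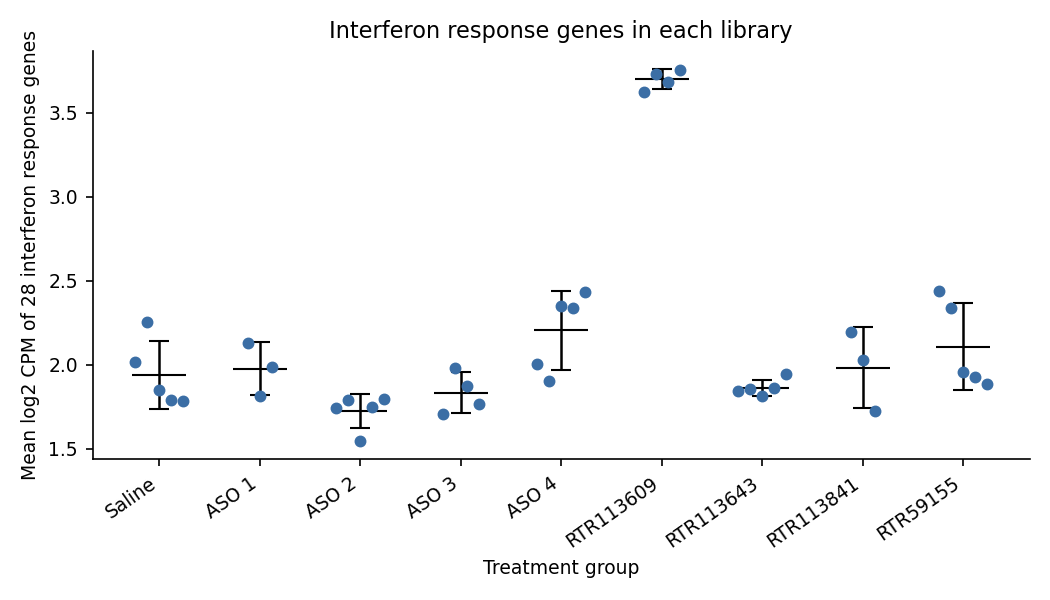
Mean log2 CPM of 28 interferon response genes (vertical axis) for each library by group, with the mean and SD of each group. RTR113609 lies at 3.70 ± 0.059 and saline at 1.94 ± 0.20.

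RTR113643 against saline gave 93 genes, 15 higher and 78 lower. Nrxn3 fell by 0.996 on the log2 scale (SE 0.064, adjusted p = 1.28e-13), Nudcd1 by 0.67 (SE 0.092, adjusted p = 2.21e-05), and Col19a1, a collagen gene, by 0.89 (SE 0.12, adjusted p = 1.28e-05); Gpc5 also fell (-0.89, SE 0.15). Rises included Acp5, the tartrate-resistant acid phosphatase gene (1.57, SE 0.35, adjusted p = 0.0225), the neuropeptide gene Cort (0.57), Trim17 (0.47) and Hunk (0.46). Of 24 disease-associated microglia genes Cd52 alone rose over all genes (1.01, adjusted p = 0.0273), and 16 were higher adjusted over the list alone (median 0.43, camera adjusted p = 1.64e-12; adjusted p = 0.747 with an estimated correlation). Of 13 complement genes C1qb rose (0.59, adjusted p = 0.0367) and 3 were higher adjusted over the list alone (camera adjusted p = 0.00778; adjusted p = 0.747 with an estimated correlation). Of 20 myelin genes Mal fell (-0.35, adjusted p = 0.00969), with 1 higher and 3 lower adjusted over the list alone. Camera called 7 of 29 lists, none with an estimated correlation. The number of lists was 8 to 12 in the fits without 1 library, with 11 without RTR113643 replicate 1 and 11, 12 and 11 without saline replicates 1 to 3. The number of genes was 38 without RTR113643 replicate 2, 49 and 55 without saline replicates 4 and 5, 171 with DESeq2, 187 with limma voom, 174 with regional covariates and 147 with the GC offset. Of 11 named calls, 1, 5, 3 and 3 ended without RTR113643 replicates 1 to 4, 4 each without saline replicates 1, 3, 4 and 5, and 1 without saline replicate 2.

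RTR113841 against saline gave 18 genes, 3 higher and 15 lower. Nrxn3 fell by 1.21 on the log2 scale (SE 0.077, adjusted p = 8.31e-14), Nudcd1 by 1.05 (SE 0.11, adjusted p = 9.69e-08) and Col19a1 by 1.07 (SE 0.14, adjusted p = 1.68e-05). Btbd16 also fell (-1.18, SE 0.22, adjusted p = 0.00729), and Thbs1, a matricellular glycoprotein gene, rose (0.88, SE 0.16, adjusted p = 0.00617) with Kdm6b (0.30) and Ppfibp1 (0.25). No list member except Tmem106b passed over all genes. None of 24 disease-associated microglia genes passed adjusted over the list alone, and their median was 0.39 (camera adjusted p = 2.74e-11; adjusted p = 0.461 with an estimated correlation). The same was true of the 10 striatum markers, with a median of -0.16 (camera adjusted p = 0.0125; adjusted p = 0.666 with an estimated correlation). Camera called 13 of 29 lists, none with an estimated correlation. Without RTR113841 replicate 1 the number of genes was 9 and Thbs1 (0.85, adjusted p = 0.0924), Btbd16 (-1.004, adjusted p = 0.269), Kdm6b and Ppfibp1 no longer passed. The fit of 2 groups only also ended 4 of 7 named calls. The regional covariates, and the fits without the high-Pmch libraries, without replicate 2 or without saline replicate 1, ended 2 each. DESeq2 called 31 genes and limma voom 28.

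RTR59155 against saline gave 117 genes, 21 higher and 96 lower. Nrxn3 fell by 1.29 on the log2 scale (SE 0.065, adjusted p = 3.27e-17), Nudcd1 by 1.19 (SE 0.095, adjusted p = 1.74e-11), Col19a1 by 1.45 (SE 0.12, adjusted p = 1.24e-10) and Plin4, a lipid droplet coat gene, by 1.54 (SE 0.29, adjusted p = 0.00223). Microglial genes rose, with 5 of 24 disease-associated microglia genes over all genes and 16 higher adjusted over the list alone (median 0.49, camera adjusted p = 1.8e-18; adjusted p = 0.304 with an estimated correlation). Itgax (1.41, SE 0.31, adjusted p = 0.0131), Ccl6 (0.99) and Cd52 (0.94) were among them, and Siglecf (0.99) and Slc15a3 (0.73) rose outside the list. Of 44 lysosomal genes Naglu (0.31) and Ctsd (0.49) rose, and 19 were higher adjusted over the list alone (camera adjusted p = 1.21e-14; adjusted p = 0.304 with an estimated correlation). Of 13 complement genes 3 rose, including C1qb (0.62) and C1qc (0.63), and 4 were higher adjusted over the list alone (camera adjusted p = 0.000363; adjusted p = 0.629 with an estimated correlation). Mal fell (-0.53, adjusted p = 6.26e-06) and Trf rose (0.36) among 20 myelin genes, where 2 were higher and 4 lower adjusted over the list alone, and F13a1 of border macrophages fell (-0.79). None of the 10 striatum markers passed over all genes or adjusted over the list alone, and their median was -0.18 (camera adjusted p = 0.00207; adjusted p = 0.629 with an estimated correlation). Camera called 10 of 29 lists (6 without RTR59155 replicate 1 or 2), none with an estimated correlation. The number of genes was 75 without RTR59155 replicate 2 or saline replicate 1, 176 with limma voom and 62 without the high-Pmch libraries, which ended 9 of 17 named calls. Leaving out replicates 1, 2, 3 and 4 of RTR59155 ended 8, 10, 6 and 5 of them, and leaving out saline replicates 1, 3, 4 and 5 ended 10, 10, 8 and 6.

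Across treatments, no more than 3 genes could be shared, since ASO 4 had 3 past the threshold. Within that limit, Tmem106b was the single gene past the threshold in all 8 comparisons and the single gene shared by ASO 1 to ASO 4. Itsn1 (chromosome 16, 91729281 to 91920597), Abl1, Mvb12b and Nrxn3 (chromosome 12, 88722876 to 90334935, a span of 1612 kb) fell with it in ASO 1, ASO 2, RTR113643, RTR113841 and RTR59155. Nrxn3 also fell in RTR113609 (-0.77, SE 0.068, adjusted p = 7.28e-11), where Itsn1, Abl1 and Mvb12b had log2 fold changes of -0.32, -0.006 and -0.12. In ASO 3 and ASO 4 the log2 fold changes of Nrxn3 were -0.19 (SE 0.067, adjusted p = 0.136) and -0.13 (SE 0.063, adjusted p = 0.558), and those of Itsn1 were 0.06 and -0.06. Ctnna2, the largest fall in ASO 3, fell by 0.40 in ASO 1, 0.80 in RTR113609, 0.36 in RTR113643 and 0.44 in RTR59155. Nudcd1 had log2 fold changes of 0.05 in both ASO 3 and RTR113609 (adjusted p = 0.848 each). ASO 1 and RTR59155 shared 30 falls where 0.170 would be shared by independent sets, ASO 1 and RTR113643 shared 23 (0.138) and RTR113643 and RTR59155 shared 49 (0.389). The same saline libraries entered both comparisons of each pair; when these were divided between the comparisons, 17, 16 and 23 falls were shared. The median span of the genes that fell was 156.5 kb in ASO 1, 115.9 kb in ASO 2, 47.5 kb in ASO 3, 55.1 kb in ASO 4, 118.8 kb in RTR113609, 101.7 kb in RTR113643, 155.1 kb in RTR113841 and 180 kb in RTR59155, against 18.6 kb for all tested genes. Spans were not compared at matched abundance.

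**Figure D4:**
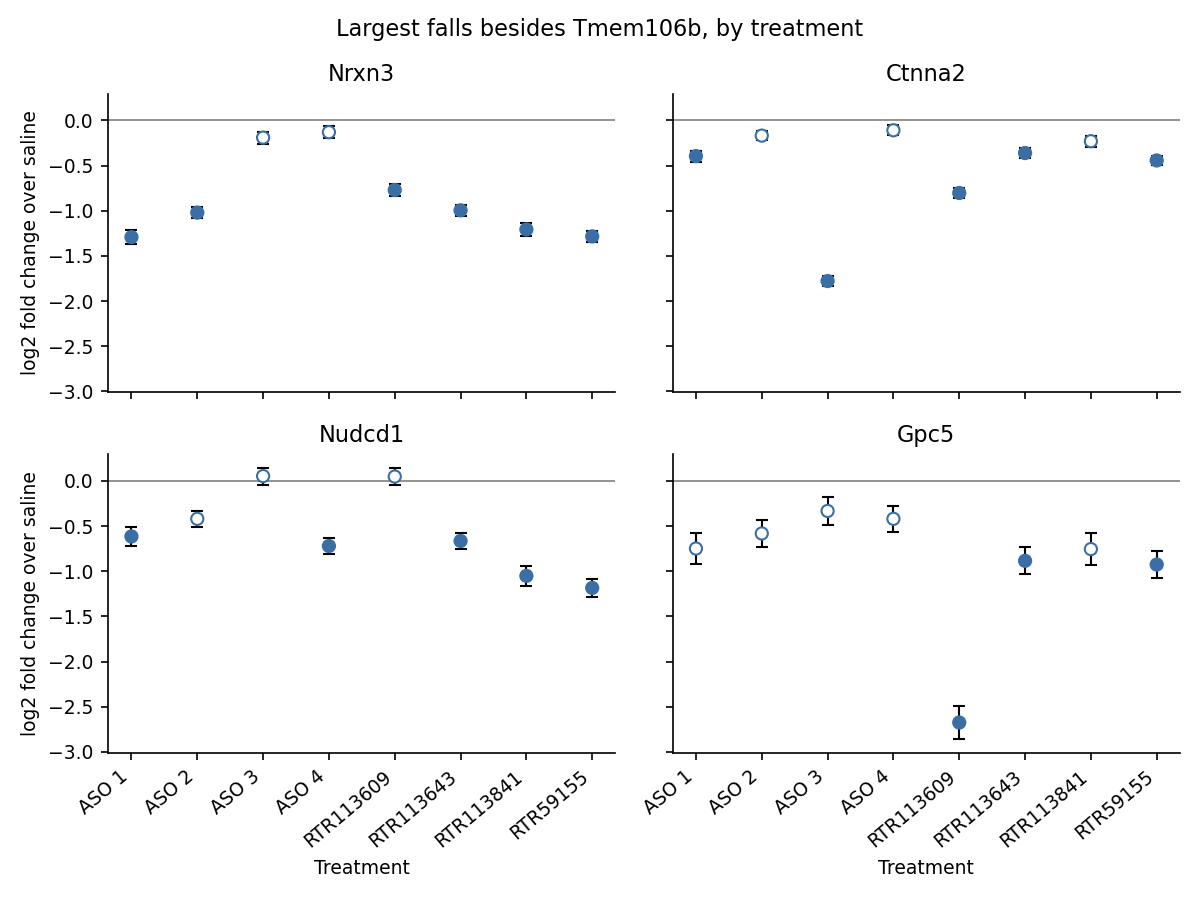
Log2 fold change against saline (vertical axis, bars show SE) of Nrxn3, Ctnna2, Nudcd1 and Gpc5 in each of 8 treatments, with filled points for an adjusted p under 0.05. Ctnna2 is lowest in ASO 3 at -1.78 and Gpc5 in RTR113609 at -2.68.

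The comparisons between ASOs asked whether the numbered ASOs differed from each other. Tmem106b was lower in ASO 1 than in ASO 2 (log2 fold change -0.75, SE 0.16, adjusted p = 0.00304) and than in ASO 4 (-1.08, SE 0.16, adjusted p = 8.33e-05), and lower in ASO 3 than in ASO 4 (-0.57, SE 0.14, adjusted p = 0.0292). It did not pass between ASO 1 and ASO 3 (-0.52, SE 0.16, adjusted p = 0.103), ASO 2 and ASO 3 (0.24, SE 0.14, adjusted p = 0.348) or ASO 2 and ASO 4 (-0.33, SE 0.13, adjusted p = 0.156). The ASO 1 and ASO 3 difference passed without the filter (adjusted p = 0.0402) and in the fit of saline and ASO 1 to ASO 4 (adjusted p = 0.0322). That of ASO 2 and ASO 4 passed with the GC offset (-0.44, adjusted p = 0.0355). The ASO 3 and ASO 4 call was lost without ASO 3 replicate 1 (-0.55, adjusted p = 0.0891) or 4 (-0.49, adjusted p = 0.173) and without ASO 4 replicate 3 (-0.57, adjusted p = 0.0562) or 5 (-0.55, adjusted p = 0.0564). The ASO 1 and ASO 2 call was lost with regional covariates (-0.66, adjusted p = 0.119), and all 3 calls were lost without the high-Pmch libraries (adjusted p from 0.435 to 0.867). That fit left 1 library each in ASO 1 and ASO 3, and its log2 fold changes were -0.82 for ASO 1 against ASO 2, -1.02 for ASO 1 against ASO 4 and -0.43 for ASO 3 against ASO 4.

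ASO 1 and ASO 2 differed in 2085 genes, 819 higher and 1266 lower in ASO 1. Higher in ASO 1 were the immediate early gene Egr2 (14.2 ± 1.86 CPM, SD, n = 3, against 4.24 ± 1.73 CPM, SD, n = 5; log2 fold change 1.72, adjusted p = 0.00162), Tmem252 (1.59) and Lhx9 (1.51). Lower were Phex (-1.02), Fgf3 (-1.02) and Hnrnpa1 (-0.92). With regional covariates 15 genes passed and all 9 named calls ended. Without the high-Pmch libraries 1 gene passed, and without ASO 1 replicates 1 and 2 and ASO 2 replicate 3 the number was 474, 489 and 960. ASO 1 and ASO 3 differed in 324 genes, 210 higher and 114 lower in ASO 1: Egr2 (2.31), Arc (1.85) and Fos (1.84) were higher, and the red cell genes Alas2 (-4.05), Hbb-bs (-3.91) and Hba-a2 (-3.72) lower. The number was 99 and 178 without ASO 1 replicates 1 and 2, 210 and 179 without ASO 3 replicates 2 and 4, 188 with 2 groups only, 203 with regional covariates, which ended the red cell gene calls, and 12 without the high-Pmch libraries, which ended all 6. ASO 1 and ASO 4 differed in 85 genes, 47 higher and 38 lower in ASO 1: Nr4a1 (1.34), Gpr3 (0.94) and Fosl2 (0.90) were higher, and Nrxn3 (-1.16, SE 0.077, adjusted p = 3.03e-13) and Pcdh9 (-1.03, SE 0.096, adjusted p = 2.77e-09) lower. The number was 36 and 51 without ASO 1 replicates 1 and 2, 130 with DESeq2, 30 with 2 groups only and 5 without the high-Pmch libraries, which ended 4 of 6 named calls.

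ASO 2 and ASO 3 differed in 1105 genes, 620 higher and 485 lower in ASO 2. Ctnna2 (1.61, SE 0.06, adjusted p = 8.25e-22), Kcnq5 (1.37, SE 0.082, adjusted p = 4.02e-15) and Phex (1.23) were higher in ASO 2, and the hypothalamic peptide genes Pomc (-2.36) and Oxt (-2.09) and Ppp1r17 (-2.09) lower. The number was 251, 440 and 441 without ASO 3 replicates 1, 2 and 4, 402 and 724 without ASO 2 replicates 3 and 5, 2366 with limma voom, 67 with regional covariates and 21 without the high-Pmch libraries; of 9 named calls, Ctnna2 and Kcnq5 alone passed in both of the last fits, and Pomc and Oxt are in the list behind the hypothalamus covariate. ASO 2 and ASO 4 differed in 357 genes, 207 higher and 150 lower in ASO 2: Phex (0.95), Egr3 (0.61) and Inhba (0.55) were higher, and Nrxn3 (-0.89, SE 0.064, adjusted p = 4.77e-12), the chemokine Ccl4 (-1.33) and the interferon response gene Ifit1 (-0.84) lower. The number was 197, 584, 18, 174 and 177 without ASO 2 replicates 1 to 5, 91 and 29 without ASO 4 replicates 4 and 5, 854 with DESeq2, 5 with regional covariates and 8 without the high-Pmch libraries, and both of the last fits ended each named call except Nrxn3. ASO 3 and ASO 4 differed in 232 genes, 80 higher and 152 lower in ASO 3: Hba-a2 (4.03), Hbb-bs (3.91) and Hba-a1 (3.65) were higher, and Ctnna2 (-1.67, SE 0.06, adjusted p = 2.47e-22), Npas4 (-1.66) and Kcnq5 (-1.196) lower. The number was 148, 147 and 100 without ASO 3 replicates 1, 2 and 4, 151 and 359 without ASO 4 replicates 3 and 4, 407 with DESeq2, 717 with limma voom, 126 with 2 groups only, 111 with regional covariates, which ended 4 of 7 named calls, and 21 without the high-Pmch libraries, which ended 5.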

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

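The tests of lower Tmem106b and of the share of striatum and hypothalamus, the GC offset, and 8 of the lists screened for libraries standing apart were chosen only after the result was seen. The number of drawn regroupings was set to 60 after smaller draws had been run and seen.

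A library stood apart from the others of its group, by a gap large against the range of the group, in 5 of 98 groups screened over 14 measures; chance gives about 1 in 20. Saline replicate 2 had 3.38 CPM of Tmem106a against 1.91 to 2.17 in the other saline libraries. ASO 3 replicate 4 had 44.2 M counts against 34.3 to 34.7 M in the others. ASO 2 replicate 3 had an interferon response list mean of 1.55 log2 CPM against 1.74 to 1.80. ASO 3 replicate 4 had a p53 target list mean of 3.86 log2 CPM against 3.72 to 3.73. RTR113643 replicate 1 had a hypothalamus list mean of 2.09 log2 CPM against 0.422 to 0.632.

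Genes with long spans fell in several treatments, and 22 genes, with spans from 13.5 to 1612 kb, fell in at least 3 of ASO 1, ASO 2, RTR113643 and RTR59155. Gene length bias of the libraries stays open. Tested genes at least as long as the median of the falls, with the least abundant left out, had a median of -0.082 at its lowest. This was in RTR113609, with a spread of 0.132 between genes, against -0.277 for the falls. The falls were chosen for being lower, so their median would lie below that of other long genes in any case. In RTR113609 24.5% of 1610 such long genes fell. The upper quartile of such long genes was 0 in ASO 1, -0.007 in RTR113609 and -0.002 in RTR59155, and from 0.029 to 0.084 in the other treatments. A lower Tmem106b as the only cause was argued against for the 22 genes, which were chosen without ASO 3 and RTR113841. Against saline their median was -0.011 in ASO 3 (quartiles -0.161 and 0.025), where Tmem106b stood at -1.334. It was -0.233 in RTR113841 (quartiles -0.477 and -0.171), where Tmem106b stood at -1.38. Whether a lower Tmem106b adds to the falls stays open. In RTR113841 against ASO 3, Tmem106b differed by -0.05 (SE 0.16, adjusted p = 0.935). A gene-by-gene criterion of at least 11 lower genes, tried first, was not met, with 10 lower and 1 higher, or 7 lower with the regional covariates. By a rule set after that miss, the 22 genes were lower as a set, by a median of -0.193 (p = 2.82e-05 by fry, limma's rotation test, which is not a permutation test). The median was -0.153 with the covariates. A different share of striatum and hypothalamus was argued against in RTR59155, where 89 of 96 falls were still lower with the covariates (median -0.344 before and -0.37 after), but it stays open in ASO 3, where 67 of 231 were (median -0.316 before and -0.238 after). Pairing of each ASO with other transcripts, which may be more frequent in long genes, stays open as a hypothesis, since no ASO sequences were used here.

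ASO 1 and ASO 2 differed in 2085 genes although 44 and 14 genes passed against saline. A GC bias of the libraries as the whole cause was argued against, since 1198 of these genes stayed past the threshold with the GC offset. The fold changes did follow GC content across 6322 genes (Spearman's rho 0.46, where genes are not independent replicates). Such a trend was not particular to this pair, as rho ranged from -0.346 to 0.515 over the 14 comparisons. With covariates for striatum and hypothalamus 15 genes passed; the median change dropped from 0.265 (SE 0.071) to 0.169 (SE 0.073) while 2065 genes kept their sign, so the calls ended mainly because the changes shrank. A different share of these regions in the tissue and an effect of the ASOs cannot be told apart for these genes, because the marker levels differ between the groups themselves. The biological explanation that the ASOs act differently was not tested apart from that.

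All 28 interferon response genes rose in RTR113609, and they were higher than in every other group too, with medians from 1.52 to 2.10. Transcripts of blood immune cells as the direct source were argued against: of 32 T cell, B cell, neutrophil and monocyte genes, none of the 15 tested passed with edgeR (smallest adjusted p = 0.0917, in Lck), the largest rise was 4.04 CPM, in Ighm, which had 47.9 CPM in saline, and the summed rise was 14.03 CPM against 312.1 CPM for the interferon genes. The rest of the 32 genes were too scarce to be tested, so a small share of such cells is not excluded. A single library as the source was argued against, since all 28 genes stayed past the threshold without any 1 library. A response of brain cells to this coded treatment, whose nature the labels do not state, may be behind the rises; as a hypothesis it stays open, since neither a sequence nor a dose was there to test it. The treatment, its preparation and the handling of its 4 libraries coincide, and no batch is given in the labels.

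Other divisions of the libraries into groups of the same sizes were fitted with the 2 groups alone. Where 126 divisions exist 60 were drawn, and elsewhere all 35 or 56 were fitted; the real division is included in each count. No other fitted division called as many genes for ASO 1 against saline (27 genes, the highest other 19; 1 of 56), ASO 2 (221 and 1; 1 of 60), ASO 3 (596 and 133; 1 of 60), ASO 4 (4 and 1; 1 of 60) and RTR113609 (1148 and 425; 1 of 60). The same held for ASO 1 against ASO 2 (1859 and 15, 1 of 56) and ASO 3 (188 and 77, 1 of 35). It also held for ASO 2 against ASO 3 (1647 and 215, 1 of 60) and ASO 4 (328 and 12, 1 of 60). For these 9 the divisions argue against chance as the source of the numbers in the fits of 2 groups, but do not exclude it. The shares were not corrected for the number of comparisons. Where 60 of 126 divisions were drawn, those not drawn leave the share uncertain. For ASO 1 against ASO 4 (30 and 49; 2 of 56) and RTR113643 (106 and 265; 2 of 60) the share was under 0.05, but another division called more genes than the real one, and for RTR113643 the divisions not drawn leave the share uncertain. The share was not under 0.05 for RTR113841 (12 and 104, 3 of 56), RTR59155 (118 and 204, 3 of 60) and ASO 3 against ASO 4 (126 and 958, 3 of 60), so the divisions leave chance open there. In the fit of all groups RTR113841, with 15 falls, and RTR59155, with 96, shared 11, where 0.0748 would be shared by independent sets. With the saline libraries divided between both comparisons they shared 9. This argues against chance for the falls they share, and not for their other calls. Divisions that called far more genes than the real one, in RTR113643, RTR113841 and ASO 3 against ASO 4, point to a structure of the samples apart from the groups.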

How the results depend on the processing

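The fits with striatum and hypothalamus covariates, without the 11 libraries with Pmch above 5 CPM and with the GC offset were chosen only after the result was seen. Of 247 values of Tmem106b under alternatives, 235 kept their direction and side of the threshold, 9 no longer passed, 3 newly passed and none reversed. Of 278 numbers of genes, 178 stayed within 1.5 times the reported number and 100 did not. Of 90 numbers of lists, 66 stayed and 24 did not. All 66 came from the 74 values of fits that left out 1 library. The 8 numbers with an estimated correlation and the 8 with fry all moved. Lists were not tested again in the other alternative fits. Scaling by median of ratios left all 29 of its Tmem106b values and numbers of genes within those bounds. The fit without high-Pmch libraries leaves ASO 1 and ASO 3 with 1 library each, a lone sample assumed to vary like the other groups. Fewer samples may account for part of its losses. For ASO 1 against ASO 2 with the regional covariates, the calls ended mainly because the changes shrank. For every other change the cause was not tested. No paired analysis was possible because replicate numbers were given in the order of the samples and link none. A sex term was not run, as all libraries were of the same sex. Depth leaves the size of a change imprecise for genes at a few counts, such as Hcrt in saline at 1 to 8 counts, and its effect on the calls was not tested.

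DESeq2 called 132 genes for ASO 1, 219 for ASO 2, 557 for ASO 3, 13 for ASO 4, 171 for RTR113643 and 31 for RTR113841 against saline, 130 for ASO 1 against ASO 4, 854 for ASO 2 against ASO 4 and 407 for ASO 3 against ASO 4. Limma voom called 269 for ASO 2, 934 for ASO 3, 187 for RTR113643, 28 for RTR113841, 176 for RTR59155, 2366 for ASO 2 against ASO 3 and 717 for ASO 3 against ASO 4. Without the filter the number was 73 for ASO 1, 59 for ASO 2 and 6 for ASO 4, and Tmem106b passed between ASO 1 and ASO 3 (-0.515, adjusted p = 0.0402). With 2 groups only it was 27 for ASO 1, 221 for ASO 2, 596 for ASO 3, 188 for ASO 1 against ASO 3, 30 for ASO 1 against ASO 4 and 126 for ASO 3 against ASO 4. With saline and ASO 1 to ASO 4 only, ASO 2 had 78 genes and Tmem106b passed between ASO 1 and ASO 3 (-0.516, adjusted p = 0.0322). With the GC offset ASO 2 had 29 and RTR113643 147 genes, and Tmem106b passed between ASO 2 and ASO 4 (-0.44, adjusted p = 0.0355).

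With the regional covariates the numbers were 26 for ASO 1, 22 for ASO 2, 121 for ASO 3, 174 for RTR113643, 15 for ASO 1 against ASO 2, and 203 for ASO 1 against ASO 3. They were 67 for ASO 2 against ASO 3, 5 for ASO 2 against ASO 4 and 111 for ASO 3 against ASO 4. Tmem106b between ASO 1 and ASO 2 was at -0.66 (adjusted p = 0.119). Of the reported genes, 23 of 44 in ASO 1, 90 of 367 in ASO 3 and 1133 of 1294 in RTR113609 stayed past the threshold. Without the high-Pmch libraries the numbers were 10 for ASO 1, 8 for ASO 2, 27 for ASO 3, and 62 for RTR59155. Between ASOs they were 1 for ASO 1 against ASO 2, 12 for ASO 1 against ASO 3, 5 for ASO 1 against ASO 4, 21 for ASO 2 against ASO 3, 8 for ASO 2 against ASO 4 and 21 for ASO 3 against ASO 4. There, 0 genes were shared by ASO 1 to ASO 4. Tmem106b no longer passed there in ASO 4 (-0.821, adjusted p = 0.0514), ASO 1 against ASO 2 (-0.824, adjusted p = 0.594), ASO 1 against ASO 4 (-1.016, adjusted p = 0.435) and ASO 3 against ASO 4 (-0.433, adjusted p = 0.867). Under an estimated correlation 0 lists were called in ASO 1, ASO 2, ASO 4, RTR113643, RTR113841 and RTR59155, 1 in ASO 3 and 2 in RTR113609. Fry called 1, 0, 6 and 2 in ASO 1 to ASO 4, 11 in RTR113609 and 0 in the other coded treatments.

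Leaving out 1 library at a time gave 19 to 118 genes for ASO 1, 5 to 25 for ASO 2, 117 to 651 for ASO 3, 3 to 5 for ASO 4, 923 to 1331 for RTR113609, 38 to 116 for RTR113643, 9 to 19 for RTR113841 and 75 to 162 for RTR59155. Between ASOs it gave 474 to 2558 for ASO 1 against ASO 2, 99 to 311 for ASO 1 against ASO 3, and 36 to 88 for ASO 1 against ASO 4. It gave 251 to 1612 for ASO 2 against ASO 3, 18 to 584 for ASO 2 against ASO 4 and 100 to 359 for ASO 3 against ASO 4. The libraries that moved these by over 1.5 times stand beside each comparison. Tmem106b ranged from -1.977 to -1.728 in ASO 1, -1.157 to -1.016 in ASO 2, -1.4 to -1.259 in ASO 3, -0.804 to -0.723 in ASO 4, and from -0.634 to -0.493 between ASO 3 and ASO 4, where 4 calls were lost, the only Tmem106b calls lost this way. The lists called were 9 to 17 in ASO 1 (9 without ASO 1 replicate 1), 5 to 8 in ASO 2 (8 without ASO 2 replicate 2), and 12 to 16 in ASO 3. They were 14 to 19 in ASO 4 and in RTR113609, 8 to 12 in RTR113643 (11 without replicate 1, 11, 12 and 11 without saline replicates 1 to 3), 10 to 14 in RTR113841 and 6 to 13 in RTR59155 (6 without replicate 1 or 2).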

Other observations

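The 2 subset tests of Nrxn3, its rank among all genes and the library values in the last paragraph were chosen only after the result was seen. Camera at the preset correlation called further lists of blood vessel, glial, fibroblast and neuronal genes in which no member passed over all genes, and none of these calls held with an estimated correlation. In ASO 4, adjusted over the list alone, 5 of 10 pericyte and smooth muscle genes were higher (median 0.15, camera adjusted p = 9.37e-06; adjusted p = 0.123 with an estimated correlation). In ASO 1, 4 endothelial genes were higher adjusted over the list alone (median 0.15, camera adjusted p = 1.85e-05; adjusted p = 0.3 with an estimated correlation). There, 5 of 14 astrocyte markers were also higher adjusted over the list alone (median 0.12, camera adjusted p = 0.000805; adjusted p = 0.384 with an estimated correlation). In ASO 2 the 12 fibroblast genes had a median of -0.20 (camera adjusted p = 0.00135; adjusted p = 0.631 with an estimated correlation). In it 3 of 12 excitatory neuron genes were higher adjusted over the list alone (median 0.13, camera adjusted p = 0.00243; adjusted p = 0.631 with an estimated correlation).

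In RTR113609, 3 of 14 genes of the list for RNase H and nucleic acid sensing rose. Ifi204, an interferon-inducible DNA sensor (log2 fold change 2.27, SE 0.31, adjusted p = 1.46e-06), and Tlr3, an endosomal receptor for double-stranded RNA (0.26, SE 0.076, adjusted p = 0.0265), were among them. Of the 14, 5 were higher adjusted over the list alone (median 0.12, camera adjusted p = 0.015; adjusted p = 0.24 with an estimated correlation). The lysosomal protease genes Ctss (0.71) and Ctsc (0.48) rose among 44 lysosomal genes, of which 4 rose and 1 fell over all genes and 5 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0373; adjusted p = 0.633 with an estimated correlation). Nefh (-0.45, SE 0.078) and Tubb3 (-0.15, SE 0.045) fell among 16 pan-neuronal genes (camera adjusted p = 0.0166; adjusted p = 0.406 with an estimated correlation), and these were also the 2 lower adjusted over the list alone.

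A hypothesis was tested that libraries which took up more of a treatment had less Tmem106b and more microglial transcripts. Over 34 treated libraries in 8 groups, with group means removed and 100000 permutations within groups, Tmem106b was related to the disease-associated microglia list mean with Pearson's r = -0.466 (permutation p = 0.00765, adjusted p = 0.0153 over 4 relations) and Spearman's rho = -0.427 (permutation p = 0.0164, adjusted p = 0.0328). Without the 2 libraries farthest from the median r was -0.363, and with the hypothalamus list mean removed it was -0.468. The homeostatic microglia list mean gave r = -0.347 (permutation p = 0.0348, adjusted p = 0.0464) and rho = -0.356 (permutation p = 0.0388, adjusted p = 0.0517), with r = -0.32 without the 2 farthest. The hypothalamus list mean gave r = 0.153 (permutation p = 0.375) and rho = 0.195 (permutation p = 0.288). The relation may also follow from other differences between libraries, since the labels give no dose or level of the treatment.

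The companion hypothesis was that such libraries also had less Nrxn3. Tmem106b was related to Nrxn3 with r = 0.833 (permutation p = 2e-05, adjusted p = 8e-05) and rho = 0.826 (permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 4e-05), and r was 0.781 without the 2 farthest libraries. In the 25 libraries of 6 treatments in which Nrxn3 fell, r was 0.875 (permutation p = 1e-05, again the smallest possible) and rho 0.892, with 0.831 without the 2 farthest. Over all 34 treated libraries Nrxn3 ranked 2 among 19245 genes by r. In the 9 libraries of ASO 3 and ASO 4, r was 0.038 (exact permutation p = 0.895 over 2880 orders) and rho 0.233 (exact permutation p = 0.518), which leaves a relation there not detected at this size. A common dependence on uptake may account for the relation in the 6 treatments, as a hypothesis found and tested on the same data.

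Hbb-bs stood at 51.2, 34.97 and 24.4 CPM in ASO 3 replicates 1 to 3 and at 7.44 CPM in replicate 4, and at 31.9 CPM in ASO 2 replicate 2, 32.1 CPM in RTR113643 replicate 4 and 15.9 CPM in RTR113609 replicate 3. Nnt, chosen after its values were seen, had 1.92 CPM in ASO 1 replicate 1 and 0.0860 to 0.528 CPM in the other 38 libraries. Gdf15, chosen likewise, had 0.545, 0.543, 0.726 and 1.398 CPM in ASO 3 replicates 1 to 4, against 0.0281 to 0.121 CPM in saline and at most 0.416 CPM in any other library. Chi-square per degree of freedom between replicates ran from 3.27 to 16.5, so no pair of libraries of a group held the same counts.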
